A study of Homo sapiens with 6 samples.

How the data were processed

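RNA of K562 cells was measured on 6 Affymetrix HG-U133 Plus 2.0 arrays, 1 sample each. The labels give 3 independent experiments, each with an siRNA and a scrambled RNA sample, under ATRA in experiments 1 and 3 and under DMSO in experiment 2. Per the labels' protocols, RNA was isolated with TRIzol and labelled with a 3' in vitro transcription kit. The deposited values are log2 expression after the RMA algorithm, run by the authors in BRB-ArrayTools per the series' design text. The version and the background and normalization settings are not given in the sources used here. The authors compared classes and pathways in the same software. Their settings and lists are not given in the sources used here. The values behaved as log2 values of uncentred arrays, with a median over all probe sets of 6.00.

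The table held 54675 probe sets, of which 62 were control probe sets. The platform annotation supplied with the series paired 41091 probe sets with 1 gene and 1801 with several, and 11721 were not listed in it and are unnamed here. Probe sets with several genes, among them some globin probe sets, were not used to name a gene. Of the genes, 19735 were found by gene identifier in a RefSeq gene table, and 0 symbols had to be updated. Each of 19775 genes was represented by the probe set with the highest mean over the 6 arrays, with no filter on dim probe sets. Gene coordinates are not given because no genome build is named. No 2 arrays held identical values.

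Tests used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The siRNA comparison used all 6 arrays with treatment as a covariate and 3 residual degrees of freedom. The comparison within ATRA and the difference of siRNA effects came from a fit of 4 groups with 2 residual degrees of freedom, in which each DMSO group is 1 array assumed to vary like the others. ATRA was compared with DMSO on the mean of the siRNA and scrambled array of each experiment, 2 against 1, with 1 residual degree of freedom. PRAME was also tested by two-sided exact permutation of the labels and of the pair signs.

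Of the gene lists, 22 for pathways and 4 of markers for other cell types were fixed with 598 members, 516 of them measured. Lists were tested with camera at a preset correlation of 0.01, with its estimated correlation and with fry beside it, over lists with at least 5 measured genes. The lists, the tests of each comparison and the rule for named genes were fixed before the data were examined, as were the alternatives other than those that the closing section says were chosen after seeing the data. The rule took PRAME, the 10 genes furthest up and the 10 furthest down among those past the threshold with the same sign in all 3 experiments, and up to 4 members of each list by smallest p. Where fewer than 10 passed, places were filled by smallest p among genes with the same sign throughout and a mean at or above the median of tested genes (6.73), and such genes are said to have missed the test. For ATRA and for the difference of siRNA effects it took 5 and up to 3, with both ATRA experiments on the same side of the DMSO experiment. The text gives a selection of the list members.

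The experiment numbers pair the samples. The labels mark them as independent experiments, and deviations from the group means correlated at 0.679, 0.795 and 0.883 between arrays of the same number across genes, against 0.402 and 0.534 between experiments 1 and 2 and -0.796 to -0.627 with experiment 3. The fit with the experiment as a block left 2 residual degrees of freedom and is given where it changes a call. With the block, the p-values rest on the spread of the siRNA differences between these 3 experiments, moderated by eBayes with values from other genes. The printed SEs are moderated too. For FN1 the SD of the 3 differences was 0.26 and the moderated SE of their mean 0.08, and for PRAME 0.15 and 0.06. The spreads of the other fits, named next, are moderated in the same way. Without it, the spread also holds differences in level between the 2 ATRA experiments. In the unblocked fit of 4 groups and in ATRA against DMSO, the spread comes from those 2 experiments alone. Comparisons of a single experiment with experiment 2 use the spread between arrays within experiments.

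Each test was tested on simulated data of 19775 genes, in which 200 were changed by a log2 difference of 0.5, 1, 2 or 4. The unblocked siRNA test recovered 6%, 84%, 98% and 100% of them in that order, with 0 false calls. The blocked one recovered 94%, 100%, 100% and 100%, with 14 false calls. The ATRA test recovered 0%, 12%, 50% and 100%, with 11 false calls, and the difference of siRNA effects 0%, 0%, 16% and 82%, with 0 false calls. With the block, the difference of siRNA effects reached 18%, 98%, 100% and 100%, but with 71 false calls. Within ATRA the shares were 0%, 20%, 82% and 100%. Changing 200 genes at once eases the adjusted threshold, so these shares can be lower where fewer genes change. In the real data CYP26A1, at 5.94 between ATRA and DMSO, missed the ATRA test (unadjusted p = 1.99e-04, adjusted p = 0.995). Alternatives covered the block, covariates, normalization, centring, moderation, array weights, dim probe sets, the choice of probe sets, the threshold, set tests and leaving out arrays or experiments. Signal over background is the limit on depth for arrays, and no detection calls were used.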

Results

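K562 is a human leukaemia line from a chronic myeloid leukaemia. The cells were nucleofected with a small interfering RNA (siRNA) or with a scrambled control RNA, each at up to 200 nM, and after 24 hours they received all-trans retinoic acid (ATRA) or its solvent DMSO. The labels name the siRNA only as RNAi8, and the series is about PRAME, a cancer-testis antigen that represses signalling through retinoic acid receptors. Total RNA was profiled on 6 human expression arrays from 3 independent experiments, with 1 siRNA array and 1 scrambled array in each. Experiments 1 and 3 received ATRA and experiment 2 received DMSO, so the siRNA group and the scrambled group held 3 arrays each. Each array gave a log2 expression value for 54675 probe sets, with array medians between 5.96 and 6.02, and 19775 genes were tested. Signals below the median of all probe sets (6.00) were not shown to be above background, and for genes at such levels, called dim, a difference is given in signal alone. Precision is limited by the number of arrays.

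Experiment 3 differed from the others in its control transcripts and across probe sets. Its arrays correlated with the other 4 at r of 0.979 to 0.982 across probe sets, which are not independent replicates, while arrays of experiments 1 and 2 correlated with each other at 0.996 or more. The actin 3' probe set exceeded the actin 5' probe set by 2.98 and 3.36 log2 units in experiment 3, against 0.63 to 0.92 on the other arrays. For GAPDH the gap was 1.20 and 0.74, against 0.03 to 0.08. The polyadenylated spike-in transcripts, added before labelling, had a median gap of 2.39 and 2.22, against 1.14 to 1.51.

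**Figure D1:**
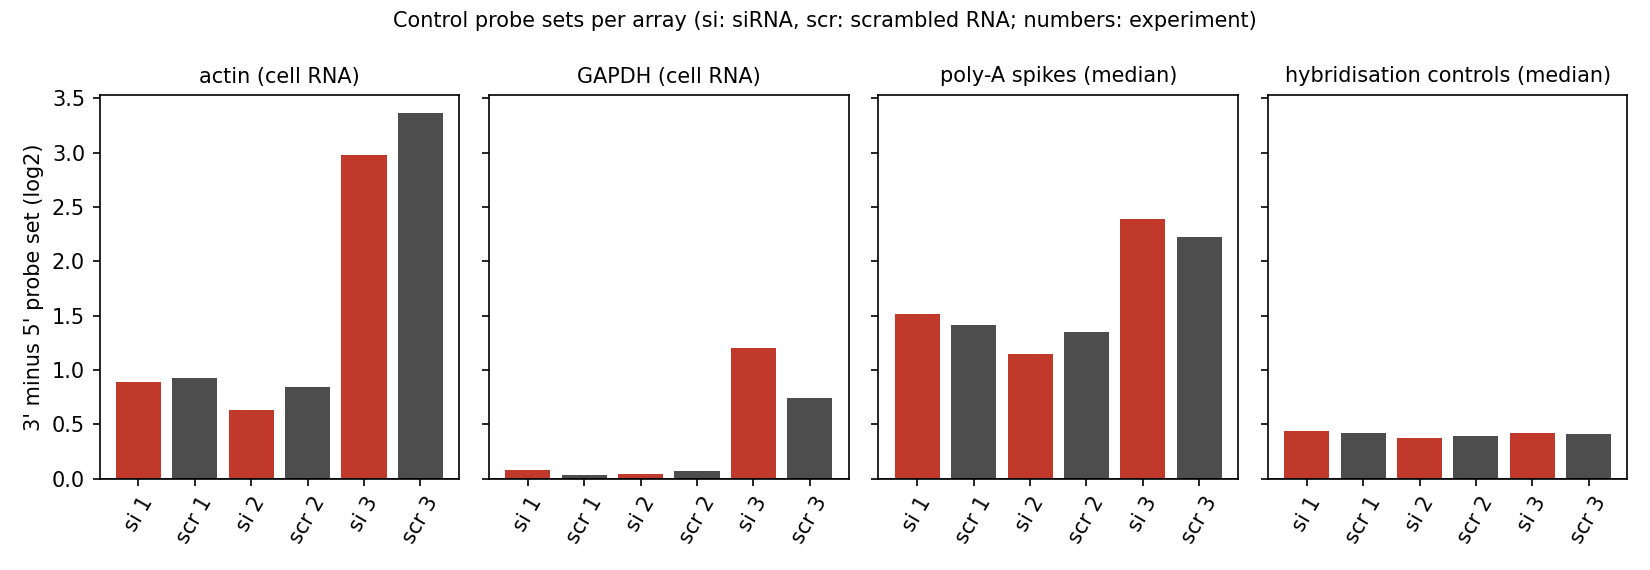
Difference in log2 signal between the 3' and the 5' probe set of control transcripts, 1 bar per array (red siRNA, grey scrambled RNA, numbered by experiment). Both arrays of experiment 3 lie above the other 4 for actin, GAPDH and the poly-A spikes (up to 3.36), and the hybridisation controls lie between 0.37 and 0.44 on all 6 arrays.

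PRAME transcript, the named target in the series, was lower with the siRNA in each of the 3 experiments. The mean log2 level was 12.12 ± 0.02 (SD, n = 3) with the siRNA and 12.90 ± 0.17 (SD, n = 3) with the scrambled RNA. The difference was -0.78, so that 58.4% of the array signal was left. No calibration of signal against transcript amount was used. The share of signal left was 54.4% in experiment 1 (ATRA), 55.4% in experiment 2 (DMSO) and 65.9% in experiment 3 (ATRA, with the larger control gaps). PRAME passed the test once each siRNA array was compared with the scrambled array of its own experiment (limma with the experiment as a block, SE 0.06, 95% interval -0.90 to -0.65, adjusted p = 9.97e-04). Without that block the same difference missed it (SE 0.10, adjusted p = 1). Over all alternatives the adjusted p ran from 1.11e-04 to 1, and with the block but without experiment 2 it was 0.142. A two-sided exact permutation test gave p = 0.1 over the 6 labels and p = 0.25 over the 3 pair signs, each the smallest value it can reach.

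Beyond PRAME, which transcripts differed between siRNA and scrambled RNA was asked over all genes. NORAD, an abundant long noncoding RNA that binds PUMILIO proteins, was lower with the siRNA in all 3 experiments, by -0.55, -0.58 and -0.42, leaving 70.0% of the scrambled level. FN1, which encodes the matrix protein fibronectin, was higher by 0.88, 0.42 and 0.87, a mean of 1.65-fold. SLC16A9, a solute carrier of the monocarboxylate transporter family, was higher by 0.58, 0.41 and 0.69. PRSS2, a trypsinogen named here after its values were seen, was lower by -0.42, -0.56 and -0.70.

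These 4 genes and PRAME passed the test with the experiment as a block, and no gene passed it without the block. In limma with treatment as a covariate and no block, 0 of 19775 genes passed and the smallest adjusted p was 1. An unadjusted p below 0.05 was reached by 255 genes, of which 159 were higher with the siRNA. Other splits of the 6 arrays into 3 and 3 gave 146 to 4249 such genes, so these counts alone show no effect of the siRNA. With the block, 2 genes rose and 3 fell, and 1268 had an unadjusted p below 0.05. The blocked differences were -0.52 ± 0.05 (SE, adjusted p = 0.00531) for NORAD, 0.72 ± 0.08 (adjusted p = 0.0232) for FN1, 0.56 ± 0.06 (adjusted p = 0.0232) for SLC16A9 and -0.56 ± 0.07 (adjusted p = 0.0323) for PRSS2. Leaving out an experiment changed these calls, but it also left fewer pairs to estimate the spread from. With the block, PRAME alone passed without experiment 1 (adjusted p = 0.0392) and FN1 alone without experiment 2 (adjusted p = 0.0272). Without experiment 3, NORAD (adjusted p = 0.0199) and PRAME (adjusted p = 0.00184) passed. Over all alternatives the adjusted p ran up to 1 for each, from 0.00202 for NORAD, 0.00875 for FN1 and SLC16A9, and 0.0127 for PRSS2. The second NORAD probe set was lower in every experiment as well (mean -0.47), and 3 further bright FN1 probe sets differed by 0.68 to 0.77. Another FN1 probe set at a level of 6.11, just above the dim range, differed by only 0.01, and the dim ones differed by 0.01 and 0.10. The second PRSS2 probe set, at a level of 6.62, was lower by less, at -0.31, -0.15 and -0.45 (mean -0.30).

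**Figure D2:**
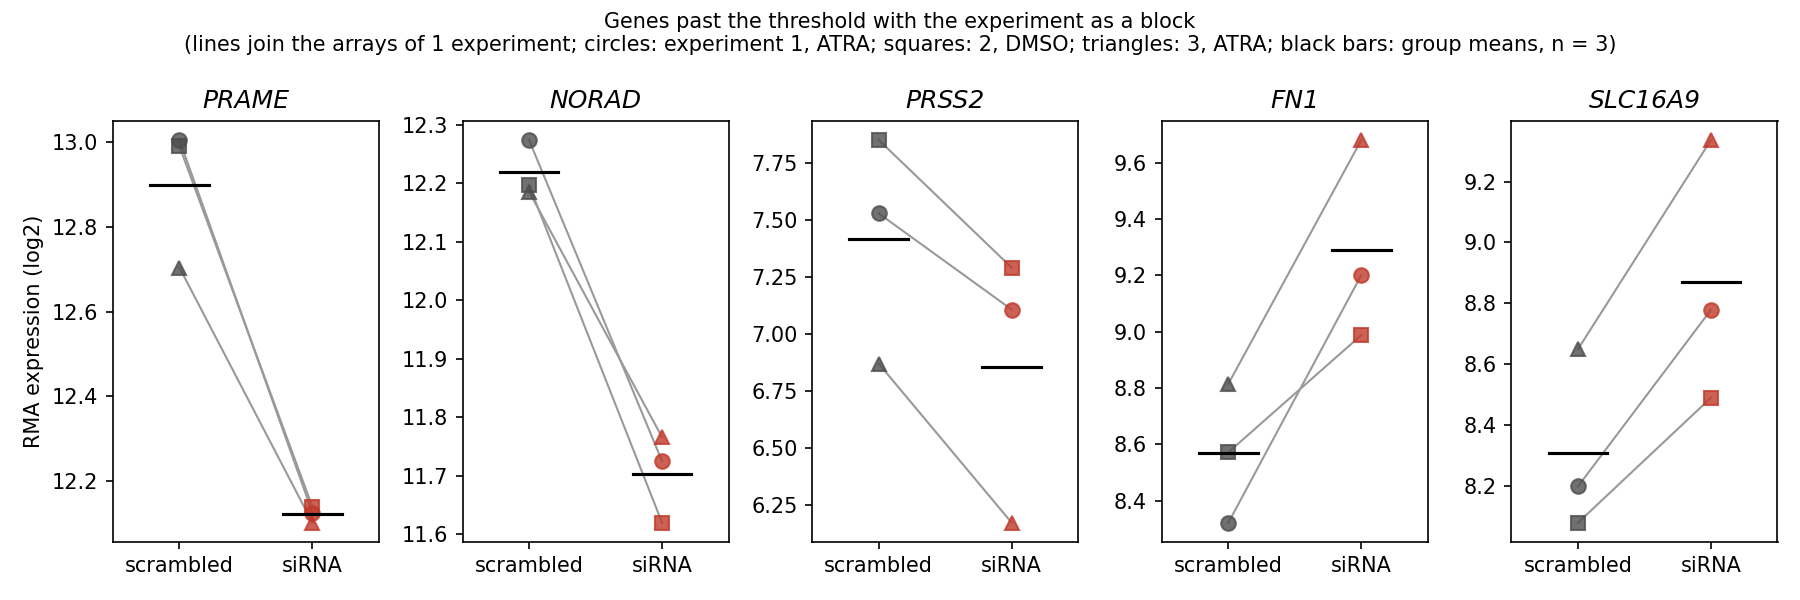
Log2 expression of PRAME, NORAD, PRSS2, FN1 and SLC16A9 on each array, with lines joining the scrambled and the siRNA array of 1 experiment and black bars at the group means (n = 3). PRAME, NORAD and PRSS2 are lower with the siRNA in all 3 experiments, and FN1 and SLC16A9 are higher in all 3.

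The genes that filled the remaining places of the naming rule, apart from list members, missed the test in both fits and had the same sign in all 3 experiments. Those higher with the siRNA included DLK1, a membrane ligand related to the Notch ligands (0.41 ± 0.15 SE), PLAT, tissue plasminogen activator (0.33 ± 0.12 SE), and both PPP1R3C (0.26) and PPP1R3B (0.23), which target protein phosphatase 1 to glycogen. CAMSAP2, a microtubule minus-end protein (0.26), BTBD10 (0.23), TRIM6 (0.23) and TESPA1 (0.16) completed that side. Those lower included GFPT1, the rate-limiting enzyme of the hexosamine pathway (-0.35 ± 0.12 SE), TLN1, the integrin-binding talin (-0.28 ± 0.10 SE), and ZFP42, a pluripotency-associated zinc finger protein (-0.24). CLEC11A (-0.22), INHBE (-0.20), HAPLN2 (-0.20), TTC7A (-0.19) and ZNF792 (-0.17) were the rest. Other probe sets of TTC7A (0.05 to 0.11) and TESPA1 (-0.06) had the opposite sign, as did 1 each of GFPT1 (0.04), TLN1 (0.05) and PPP1R3B (-0.04), and those of DLK1 (-0.00) and PPP1R3C (0.04) were near 0.

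Retinoid genes and differentiation programmes, the subject of the series, did not pass as groups under the siRNA. Of 18 retinoid receptor and handling genes, 14 were higher and 4 lower with the siRNA (camera adjusted p = 0.199), led by ALDH1A1, a retinaldehyde dehydrogenase (0.34 ± 0.10 SE), and RARB, a retinoic acid receptor (0.16 ± 0.08 SE), both dim. Of 21 retinoic acid-induced genes, 9 were higher and 12 lower (adjusted p = 0.598), among them TGM2, a transglutaminase (-0.12), and the dim HIC1 (-0.11). The granulocytic and monocytic list divided 15 to 15 (adjusted p = 0.909), with the G-CSF receptor gene CSF3R at 0.11 and the monocyte marker MNDA, which was dim, at -0.15. Of 27 erythroid genes, 10 were higher and 17 lower (adjusted p = 0.368), with embryonic zeta globin HBZ at -0.20, beta globin HBB at -0.15 and the erythroid factor KLF1 at 0.18. Of 18 megakaryocytic genes, 12 were higher (adjusted p = 0.509), with the integrin gene ITGB3 at 0.09. The Polycomb and CUL2 ligase list, to which known partners of PRAME belong, had 4 of 12 higher (adjusted p = 0.509), with EZH1 at -0.14 and JARID2 at -0.14. Among 14 cancer-testis antigens, PRAME was the only member past the threshold adjusted over the list alone without the block, and MAGEC2 stood at 0.13 (list adjusted p = 0.909).

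Proliferation, stress and metabolic lists were tested in the same way over the siRNA. Of 32 ribosomal protein genes, 27 were lower, with a median of -0.03, RPL11 at -0.10 and RPS24 at -0.08. That list had the smallest value without the block (adjusted p = 0.0960) and was the 1 list of 26 past the threshold with it (adjusted p = 0.0434). The call was lost with an estimated correlation (p = 0.513, adjusted p = 0.914) and by fry (p = 0.388), and the number of its members above 0 was 21 in experiment 1, 9 in experiment 2 and 3 in experiment 3. Without experiment 3, G2/M genes passed as lower and replication-dependent histones as higher instead (adjusted p = 0.00570 each; p = 0.402 and 0.161 with an estimated correlation). Without the siRNA array of experiment 1, ribosomal proteins (adjusted p = 1.18e-04; p = 0.229 with an estimated correlation) and oxidative phosphorylation genes (0.00258; p = 0.216) passed as lower. None of these calls held with an estimated correlation or by fry. Of 38 nuclear-encoded oxidative phosphorylation genes, 26 were lower (adjusted p = 0.247), with COX5B at -0.11. G1/S and replication genes were higher in 19 of 29 (adjusted p = 0.680; CCNE2 at 0.15), G2/M genes in 9 of 30 (adjusted p = 0.872; CCNB1 at 0.12), and cell cycle inhibitors in 5 of 13 (adjusted p = 0.909; CDKN1A at -0.05). Apoptosis genes were lower in 19 of 28 (adjusted p = 0.509; BMF at -0.16), and interferon and double-stranded RNA response genes in 17 of 33 (adjusted p = 0.680; the dim IFIH1 at 0.11). Amino acid and unfolded protein stress genes were lower in 16 of 23 (adjusted p = 0.368; DDIT3 at -0.18), and heat shock genes higher in 10 of 13 (adjusted p = 0.509; DNAJA1 at 0.14). Immediate early genes were lower in 12 of 20 (adjusted p = 0.890), although FOS stood at 0.42 ± 0.19 (SE), and BCR-ABL, STAT5 and MAPK output genes were higher in 13 of 23 (adjusted p = 0.732; SOCS2 at 0.13). Cholesterol synthesis genes were lower in 9 of 16 (adjusted p = 0.509; HMGCS1 at -0.22), glycolysis and hypoxia genes in 16 of 29 (adjusted p = 0.509; BNIP3L at -0.25), replication-dependent histones in 6 of 12 (adjusted p = 0.680; H2AC6 at 0.23) and NF-kB targets in 8 of 21 (adjusted p = 0.979; IL6 at -0.24).

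No list passed with an estimated correlation or by fry, with or without the block. Adjusted over the list alone with the block, and among genes that missed the threshold over all genes, ALDH1A1, RHAG, THBS1, FOS and H2AC6 passed on the higher side and HBZ and HMGCS1 on the lower side. THBS1 was chosen after its values were seen. Its probe set used here differed by 0.69, while its other probe sets, most of them dim, ranged from -0.15 to 0.16. Among those, one at a level of 6.16 differed by -0.01. Medians and means had opposite signs for the retinoic acid-induced, granulocytic, cancer-testis and cell cycle inhibitor lists and for the B lymphocyte and stromal markers. For NF-kB targets the test without the block pointed down although median and mean were above 0. Markers of cell types foreign to a K562 culture had medians close to the 6.00 of all probe sets, at 5.75 for T and NK lymphocytes, 5.93 for B lymphocytes, 5.85 for stroma and 6.21 for epithelium. Single members were bright, namely EPCAM (11.54), CD3D (10.08), COL1A1 (8.41) and CD79A (7.09). Under the siRNA the camera adjusted p was 0.199 for T and NK lymphocytes, 0.736 for B lymphocytes, 0.890 for stroma and 0.732 for epithelium.

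Whether the siRNA acted in ATRA-treated cells was asked in experiments 1 and 3 alone. PRAME differed there by -0.74 and FN1 by 0.87, and 0 genes passed in the fit of 4 groups, with 201 at an unadjusted p below 0.05. With the experiment as a block, FN1 alone passed (adjusted p = 0.0266) and 1162 genes had an unadjusted p below 0.05.

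Whether the siRNA effect depended on ATRA was asked by the difference between its effect under ATRA and under DMSO. CYP26A1, the cytochrome P450 that degrades retinoic acid, was higher with the siRNA by 0.25 and 0.36 in the ATRA experiments and by 0.03 under DMSO. That makes a difference of 0.27, with a 95% interval of -1.54 to 2.09 without the block and 0.01 to 0.54 with it (adjusted p = 0.998 with it). DHRS3, a retinaldehyde reductase, differed by 0.12 and 0.09 under ATRA and by -0.18 under DMSO, a difference of 0.28 (95% interval -0.76 to 1.33 without the block and 0.02 to 0.55 with it, adjusted p = 0.998 with it). Of the genes that the rule took on the positive side, the smallest p belonged to H3-3A, a gene of histone H3.3, at 0.35 under ATRA and -0.48 under DMSO, a difference of 0.83 ± 0.27 (SE). RP2 (0.55), SPRTN, a protease of DNA-protein crosslink repair (0.41), PIK3R3, a PI3-kinase regulatory subunit (0.33), and PHF2P1 (0.31) followed. On the negative side stood SBF1 (-0.44), C1RL (-0.40), TFAP2E (-0.39), ACSF2 (-0.38) and CAMK2A (-0.35).

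No gene passed that test. Of 19775 genes 0 passed with or without the block, and 262 without it and 655 with it had an unadjusted p below 0.05. Among list members, the retinoic acid-responsive RARRES1 and RARRES2 each differed by -0.35 and ALDH1A1 by 0.31. In the granulocytic list CSF2RA differed by -0.31 and FPR1 by -0.30, and in the cell cycle inhibitor list CDKN2D differed by -0.37 and RBL1 by 0.32. Of these, RARRES1, RARRES2, ALDH1A1, CSF2RA and CDKN2D were dim. PRAME itself differed by 0.11 (95% interval -0.55 to 0.77). In simulated data this test without the block found 16% of genes that differed by 2 log2 units and 82% of those that differed by 4.

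ATRA-treated cells had far more CYP26A1 than DMSO-treated cells. Its level was 11.33 in experiment 1 and 12.03 in experiment 3 (ATRA), against 5.74 in experiment 2 (DMSO), a difference of 5.94 ± 0.42 (SE; 2 ATRA experiments, 1 DMSO experiment) in log2 signal. PDK4, a pyruvate dehydrogenase kinase that turns cells from glucose towards fat oxidation, differed by 2.92 ± 0.24 (SE) in signal. Its DMSO level was dim (5.46), as was that of CYP26A1. PLAT differed by 1.48 ± 0.21 (SE). NMU, the neuropeptide neuromedin U, differed by 1.00 ± 0.15 (SE) and PPP1R3B by 0.96 ± 0.15 (SE). On the lower side were AQP3, an aquaglyceroporin (-1.12 ± 0.33 SE), the early activation marker CD69 (-0.98), ID1, an inhibitor of bHLH factors (-0.90), TENT5C, a poly(A) polymerase (-0.77), and CRYBG1 (-0.52).

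No gene passed the planned test of ATRA against DMSO, in which the experiment is the replicate. Of 19775 genes 0 passed in limma on the 3 experiment means, 235 had an unadjusted p below 0.05 and the smallest adjusted p was 0.995, the value for CYP26A1. With all 6 arrays and the experiment as a random block, CYP26A1 (adjusted p = 0.00656) and PDK4 (adjusted p = 0.0351) passed. The random block assumes 1 correlation for all genes (0.572), so it still partly counts both arrays of an experiment as replicates. With no block KIT and NMU passed as well, but that fit counts both arrays of an experiment fully as separate replicates. In either fit the treatment varies only between experiments. Over all alternatives the adjusted p of CYP26A1 ran from 8.46e-14 to 1.00. The lowest value came from experiment 3 against experiment 2 alone, where the replicates are arrays of the same experiment. The average of all PDK4 probe sets differed by 1.21. Under DMSO the signals of CYP26A1 (5.74) and PDK4 (5.46) lay below the median of all probe sets (6.00) and were not shown to be above background, so these differences in signal are lower bounds for the difference in transcript. All DMSO arrays came from 1 experiment, so ATRA and that experiment cannot be told apart.

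**Figure D3:**
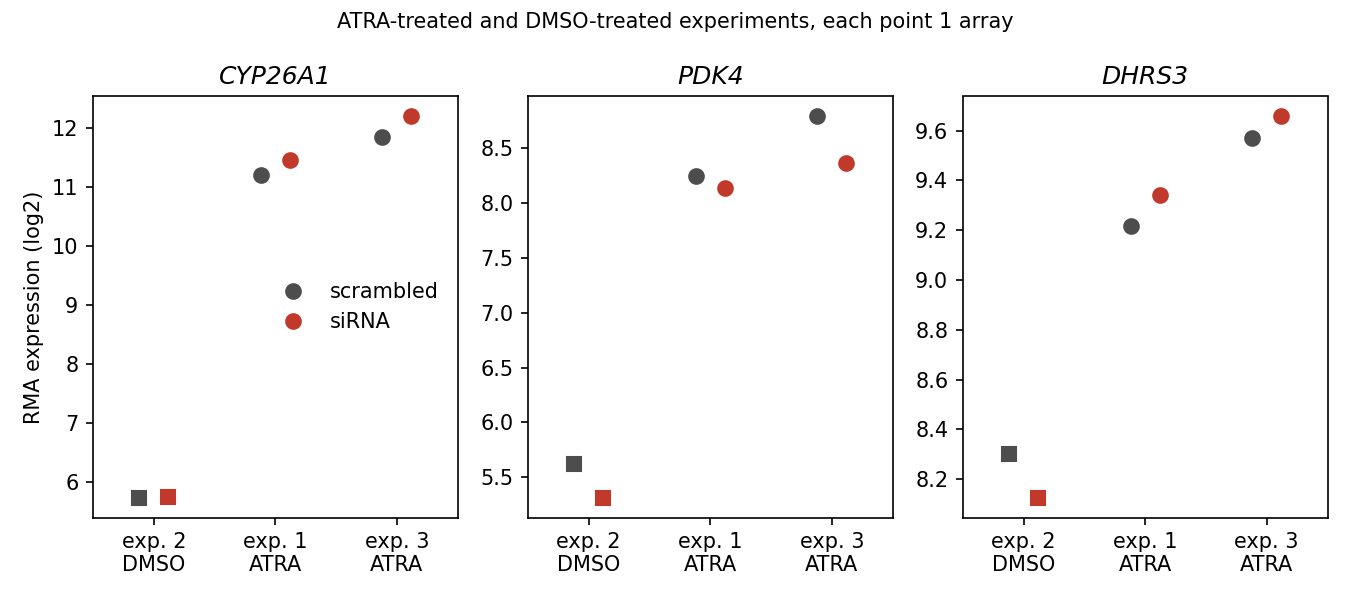
Log2 expression of CYP26A1, PDK4 and DHRS3 on each array (grey scrambled RNA, red siRNA; squares DMSO, circles ATRA), by experiment. For CYP26A1 the 4 ATRA arrays lie between 11.21 and 12.21 and the 2 DMSO arrays at 5.72 and 5.75.

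Set against experiment 2 alone, experiment 1, whose control transcripts had similar gaps, gave 132 genes past the threshold, of which 101 were higher under ATRA and 31 lower. That comparison was added after the data were examined, and its replicates are arrays of 1 experiment on each side, so it compares these experiments. Values of experiment 3 given here are against the same DMSO arrays, so they are not independent of that choice of genes. Of the 132 genes, 21 had the opposite sign in experiment 3, among them CDC42BPA (0.55; -1.73) and GATAD1 (0.43; -2.11), chosen after their values were seen. Named after their values were seen, ABCA1, the cholesterol efflux pump, was higher by at least 3.58 (adjusted p = 1.23e-04), and by at least 2.02 in experiment 3, from a dim DMSO level of 5.67. Among other genes chosen after their values were seen were SCD, stearoyl-CoA desaturase (0.75; 0.85 in experiment 3), SREBF1, its transcriptional regulator (0.75; 0.88), and ACACA, acetyl-CoA carboxylase (0.61; 1.07). HOXB3, a homeobox gene (0.59; 0.66), was higher too, and KIT, the stem cell factor receptor (-0.97; -0.98, both from ATRA levels that were dim), MS4A3, a granulocyte precursor protein (-0.59; -1.06), and LMO2, a haematopoietic transcription cofactor (-0.45; -0.40), were lower. The same comparison for experiment 3, whose control transcripts had the larger 3' to 5' gaps, gave 6777 genes.

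CYP26A1 stood apart from the other retinoid genes under ATRA, and neither retinoid list passed as a group. Of 18 retinoid receptor and handling genes 9 were above and 9 below DMSO (median -0.01, mean 0.40; camera adjusted p = 0.340), and of 21 retinoic acid-induced genes 9 were above and 12 below (median -0.02, mean 0.39; adjusted p = 0.529). DHRS3 was higher by 1.24 ± 0.31 (SE) and THBD, thrombomodulin, by 0.77 ± 0.12 (SE), a lower bound since its DMSO level of 5.85 was also below the median of all probe sets. Adjusted over the list alone, CYP26A1 passed in both lists and THBD in the second. Chosen after their values were seen, the receptor genes RARA (-0.05), RARB (-0.07), RARG (-0.09) and RXRA (-0.14) and the retinoid target TGM2 (0.04) differed by less than their SE.

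G1/S and replication genes were the 1 list past the threshold for ATRA against DMSO, with 26 of 29 higher (median 0.18, adjusted p = 0.0310), among them POLA1, a subunit of DNA polymerase alpha (0.62), E2F2 (0.42) and the helicase gene MCM3 (0.28). The call was lost with an estimated correlation (p = 0.519, adjusted p = 0.950) and by fry (p = 0.629), and over its alternatives the adjusted p ran from 0.0654 among genes at or above the median of all probe sets to 0.955 by fry. Experiment 1 alone against experiment 2 had 19 of 29 higher (adjusted p = 0.206) and experiment 3, with its larger control gaps, had 25 of 29. In experiment 1 alone, amino acid and unfolded protein stress genes were higher in 17 of 23 (adjusted p = 2.32e-04; p = 0.128 with an estimated correlation), with the cystine transporter SLC7A11 at 0.53 and the chaperone HSPA5 at 0.35. Cholesterol synthesis genes were lower there in 13 of 16 (adjusted p = 0.00827; p = 0.170 with an estimated correlation), with MSMO1, chosen after its values were seen, at -0.56. In experiment 3 only 8 of those 16 were lower and MSMO1 stood at 0.49, and stress genes were higher in 14 of 23. In the planned test these lists had adjusted p values of 0.0875 and 0.934.

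Differentiation lists did not pass under ATRA. Granulocytic and monocytic genes were lower in 19 of 30 (adjusted p = 0.340), with the monocyte receptor CD14 at -0.24 and S100A9 at 0.16, both dim. Erythroid genes were lower in 15 of 27 (adjusted p = 0.934), with ALAS2, the first enzyme of erythroid haem synthesis, at -0.44 ± 0.13 (SE), and megakaryocytic genes in 10 of 18 (adjusted p = 0.934), with the thrombin receptor F2R at 0.42. Immediate early genes were higher in 13 of 20 (adjusted p = 0.136), with KLF4 at 0.59 ± 0.13 (SE) and JUN at 0.59 ± 0.28 (SE), and heat shock genes in 9 of 13 (adjusted p = 0.340), with DNAJB4 at 0.64. Interferon response genes were lower in 19 of 33 (adjusted p = 0.789), with RSAD2, an antiviral enzyme, at -0.85 ± 0.15 (SE) and IFIT3 at 0.45. Oxidative phosphorylation genes were lower in 32 of 38 (adjusted p = 0.338; COX8A at -0.23), and adherent epithelial markers in 6 of 8 (adjusted p = 0.338). G2/M genes (20 of 30 higher, BUB1 at 0.36) and replication-dependent histones (9 of 12 lower) each had an adjusted p of 0.529, and glycolysis and hypoxia genes (20 of 29 higher, the dim ENO2 at 0.22) one of 0.461. Ribosomal proteins were lower in 23 of 32 (adjusted p = 0.559), T and NK lymphocyte markers in 8 of 11 (adjusted p = 0.736) and NF-kB targets in 11 of 21 (adjusted p = 0.934). The Polycomb and CUL2 list (adjusted p = 0.907), apoptosis genes (0.934; APAF1 at 0.72), BCR-ABL, STAT5 and MAPK output (0.934; SOCS1 at -0.80), B lymphocyte markers (0.934), cell cycle inhibitors (0.941; GADD45A at -0.73), stromal markers (0.941) and cancer-testis antigens (0.941) did not pass either. Cancer-testis antigens, apoptosis genes and cholesterol synthesis genes had medians and means of opposite sign, and for stromal markers the test pointed up although both were below 0.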

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

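The tests on experiment 3 were chosen after the result was seen.

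The controls, which no comparison used, set experiment 3 apart. The actin 3' minus 5' gap was 2.98 on its siRNA array and 3.36 on its scrambled array, and the median gap of the poly-A spikes was 2.39 and 2.22, above the other 4 arrays in each case. ATRA cannot be the whole reason, since experiment 1, also under ATRA, correlated better with DMSO experiment 2 than with experiment 3 (r higher by 0.0153). Degraded cell RNA alone is argued against by the spikes, which never passed through the cells, as their lowest gap in experiment 3 exceeded the highest elsewhere by 0.709, beyond the range of 0.37 among the other arrays. A shorter product of reverse transcription or amplification is a candidate explanation, because the gap was large in cell transcripts and spikes and the hybridisation controls, added after labelling, differed by only 0.00728. The 18S rRNA signal was also lower in experiment 3, at 9.43 and 9.20 against 11.68 to 12.40 on the other 4 arrays, and the reason was not tested. No other biological explanation was tested, and some RNA degradation on top of a shorter product stays open.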

How the results depend on the processing

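The alternatives that combine the block or a left-out array or experiment with another choice, and the comparisons of single experiments, were chosen after seeing the data. Only 1 result passed its planned test over all genes or lists, the G1/S and replication list under ATRA, and it did not change direction. Of 756 values of named genes under alternatives, 64 had the opposite sign, 59 in other probe sets of the gene and 5 when an experiment was left out. PRAME level was below 0 under all 19 alternatives (-0.87 to -0.70; without single arrays or experiments -0.87 to -0.70, with the block -0.86 to -0.73), and it passed with the replicate block (-0.78), without experiment 1 (-0.73) or 3 (-0.86), where the treatment term is by construction the same as the block, and with array weights. For siRNA against scrambled, 0 genes passed in the planned fit, 5 with the replicate block, 2 at an unadjusted p under 0.001, and 0 to 2 when arrays or experiments were left out. Array weights gave 1652, with weights of 6.78 on both DMSO arrays and at most 0.60 on the others. With the block, 1 to 2 genes passed without single experiments, 6 among genes at or above the median and 6 after quantile normalization (the same 5 and THBS1), and 1 (PRAME) with the mean of all probe sets, without the trend or over all probe sets one by one. For siRNA against scrambled within ATRA the block gave 1 gene. ATRA against DMSO gave 0 genes, 2 with a random replicate block, 4 with no replicate block, 132 for experiment 1 against experiment 2 alone and 6777 for experiment 3 against experiment 2 alone. For gene lists, siRNA against scrambled, 0 lists passed, 1 among genes at or above the median and 1 with the replicate block (ribosomal proteins in both), and 0 to 2 when arrays or experiments were left out (with or without the block, 2 without experiment 3, G2/M genes and replication-dependent histones). For gene lists, ATRA against DMSO, 1 list passed, 0 with an estimated correlation, fry, quantile normalization, the mean of all probe sets or genes at or above the median, and 2 for experiment 1 against experiment 2 alone. Apart from the treatment term without experiment 1 or 3, the cause of these changes was not tested. The difference of siRNA effects stayed at 0 genes under all its alternatives. For single gene lists 706 values kept their side of the threshold, 10 came past it and 6 lost it. No named gene passed its planned test over all genes, so none could lose a call. Of their values, 672 kept their side, 7 came past the threshold and 77 moved, all from other probe sets of the gene. Leaving out an ATRA experiment leaves 1 against 1 for ATRA against DMSO and gives values with no test. Dim genes are limited by signal over background: only 12850 of 19775 genes reached the median of all probe sets.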

Other observations

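Of the tests in this part, those on PRAME and NORAD, and the size expected from CYP26A1, were chosen after the result was seen. The test on the genes that differed with ATRA and the counts over regroupings of the arrays were set before their results. The genes of the former came from a comparison added after the data were examined.

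Across all genes the siRNA differences of the 3 experiments had little in common. Their correlation across genes, which are not independent replicates, was 0.01 between experiments 1 and 2, 0.10 between 1 and 3 and 0.09 between 2 and 3. The SD of the differences was 0.12, 0.12 and 0.16 log2 units. With no test of a difference between experiments, G2/M genes were above 0 in 16 of 30 in experiment 1, 5 in experiment 2 and 24 in experiment 3, ribosomal protein genes in 21, 9 and 3 of 32, and cell cycle inhibitors in 9, 7 and 8 of 13. Some genes appeared on both axes: PLAT and PPP1R3B were among the genes named for the siRNA (0.33 and 0.23) and for ATRA (1.48 and 0.96), while INHBE was lower with the siRNA (-0.20) and higher in experiment 1 than in experiment 2 (0.56).

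Lower PRAME came with lower NORAD. A difference in labelled length as the whole cause in every pair is argued against by experiment 1, where the gaps of actin and GAPDH differed by at most 0.05 between the arrays and PRAME still differed by -0.88 (SE of a single pair 0.10) and NORAD by -0.55 (SE 0.08). A part in experiments 2 and 3, or another difference in RNA between the arrays of a pair, stays open, since the actin gap was smaller with the siRNA in all 3 pairs (-0.03, -0.22 and -0.38) and the 18S rRNA signal higher (0.36, 0.24 and 0.23), while the GAPDH gap went both ways (0.05, -0.03 and 0.46). Direct binding of NORAD by the same siRNA is a possible explanation that these values cannot test. All 6 NORAD differences, from its 2 probe sets in 3 experiments, were below 0, but any cause of lower NORAD would give that. The naming rule also required the same sign in all 3 experiments. Direct binding cannot be told apart from an effect of PRAME loss, because 1 siRNA was used and its sequence is not given in the sources used here.

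CYP26A1 was higher with the siRNA in both ATRA experiments, which raised the hypothesis that knockdown of PRAME may enlarge the response to ATRA. The 132 genes that differed between experiments 1 and 2 were turned to their ATRA direction, and their median siRNA difference in experiment 3 was -0.0210, with 59 of them in that direction and a percentile of 8.08 among 10000 random lists matched on expression. The test asked for a median above 0.0340, and this was not met. Enlargement of all of them in proportion to CYP26A1 in experiment 3 would give at most 0.0315, since its DMSO level is dim. The observed median lay 0.0525 below that, beyond the half-width of 0.0329 of the central 95% of random lists. The expected median is itself below the required 0.0340, so enlargement at that size could not have met the test. Random lists are also a poor yardstick here, since these genes reached percentile 99.97 in experiment 2, which had no ATRA. Experiment 3 is moreover 1 pair of arrays, and the SD between the genes was 0.21. Whether knockdown enlarges the response at that size, at a smaller one or in fewer genes stays open. The median siRNA difference of these genes, turned the same way, was 0.02 in experiment 1 (percentile 81.1) and 0.01 in experiment 2 under DMSO. PDK4 was lower with the siRNA in both ATRA experiments in 2 of its 3 probe sets. The values were -0.10 and -0.43 in the brightest and -0.16 and -0.49 in a dim one. Another dim PDK4 probe set was higher (0.19 and 0.22).

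Regrouping the arrays had few possibilities. For the siRNA comparison without a block, the 10 splits of 6 arrays into 3 and 3 all gave 0 genes past the threshold, the real one and the highest other alike, and 10 splits are too few for a share under 0.05. With the block, the real assignment gave 5 genes and the highest of the other swaps within pairs gave 0, so 1 of 4 assignments gave as many, and 4 are too few for a share under 0.05. At an unadjusted p below 0.05 the real split gave 255 genes and splits that put both arrays of experiment 1 with an array of experiment 2 gave 4249 and 3711, which points to the structure of the experiments.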
